A study of Mus musculus with 25 samples.

How the data were processed

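The study measured RNA by sequencing in 25 mouse libraries. Per the labels' protocols, 11 came from spinal cord astrocytes, 6 from whole injured spinal cord and 8 from cultured brain astrocytes. The astrocytes carried a red fluorescent reporter, tdTomato, switched on in cells that express or once expressed a Gfap-driven recombinase, and were taken by fluorescence-activated sorting after the tissue was digested and its myelin removed. The injury was a contusion of 60 kdyn at thoracic level T9. Sorted libraries came from sham animals (3), from 7 days after injury (3), from 1 month (3) and from 3 months (2). Sham animals had only the bone over the cord opened and were taken at 7 days, so the later groups differed from sham in age and time after surgery as well as in injury. Tissue libraries came from 1 month (3) and 3 months (3) after injury. Each sorted or tissue replicate pooled 3 mice. The cultures came from pups of postnatal day 4 to 7, were infected with a control lentivirus or with a knockdown lentivirus against Zeb2os or against Zeb2, and were selected with puromycin at 1 µg/ml. Selection began later after infection in the Zeb2 set, and the labels give different lengths of selection for the Zeb2os set in different places, so both conditions may separate the 2 sets. Each of these 4 culture groups had 2 libraries. Nothing in the labels says that they were separate cultures, so p-values for the cultures measure only the spread between these samples, which may be technical.

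The deposited values were whole-number read counts per gene in 4 tables, 1 per sample kind, and the authors had not normalised them. Per the submitters' processing notes, FastQC, TopHat2 2.1.0, Cufflinks 2.2.1, DESeq2 and the mouse build mm10 were used, with no role or order given. The counting program, the annotation and the handling of strand were not given in the sources used here. The library kit named in the labels' protocols marks strand. Without a stated strand setting, genes that overlap on opposite strands were treated as uncertain, and so were near-identical gene copies such as the haemoglobin and ribosomal protein genes. Zeb2 lies on the minus strand of chromosome 2 at 44983632 to 45117395 in GRCm38, and Zeb2os on the plus strand at 45110707 to 45114087, inside the Zeb2 gene. Of 1990 exonic bases of Zeb2os, 653 (32.8%) overlapped exons of Zeb2. The sorted table listed 43693 genes, of which 21882 were coding and 21811 long non-coding. Of 33489 Ensembl identifiers, 33340 matched the reference by base identifier. A part of the identifiers in the Zeb2 table, holding 0.00161% of its counts, had no match and was not used here.

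Total counts ran from 15.7 to 50.2 M in sorted libraries, from 15.4 to 27.1 M in tissue, from 45.6 to 158 M in the Zeb2os set and from 29.0 to 65.4 M in the Zeb2 set. Each table was fitted on its own. Genes passed edgeR's filter at a minimum count of 10, libraries were scaled by trimmed mean of M values (TMM), and groups were compared with edgeR 4.0.16's quasi-likelihood F test in R 4.3.3. A gene was called, and is said to have risen, fallen or changed, at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. Each p given for a gene is this adjusted p unless another tool is named. All 4 sorted groups shared a fit and its estimate of spread. Expression values are counts per M (CPM) computed from the deposited counts with the TMM-scaled totals of the fit, as mean ± SD over the libraries of a group, and log2 changes are given with their standard error (SE). The common biological coefficient of variation was 0.63 in the sorted set, 0.137 in tissue, 0.321 in the Zeb2os set and 0.399 in the Zeb2 set.

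The test was checked on simulated counts with 200 changed genes per comparison. Of the 2-fold and 8-fold changes, it recovered 15% and 59% for 7 days against sham, 13% and 55% for 3 months against sham, 70% and 98% in tissue, 16% and 79% in the Zeb2os set, and 2% and 70% in the Zeb2 set. Of its calls in these simulations, 2 of 76, 5 of 73, 12 of 180, 7 of 102 and 15 of 87 were false, in the same order. This share was above the threshold of 0.05 in all but the first. A missed call in the sorted and cultured sets therefore says little about changes near 2-fold.

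A total of 32 gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, a preset correlation between genes of 0.01, both directions, and Benjamini-Hochberg adjustment over the lists of a comparison. Lists with fewer than 5 tested genes were left out of a comparison. The test was repeated with the correlation estimated from the data. For each list, calls were also counted after adjusting p over its members alone, reported as adjusted over the list alone. The lists were pan-reactive, A1-type and A2-type reactive astrocyte genes, mature astrocyte function, cholesterol synthesis, cell cycle, chondroitin sulfate proteoglycans and tenascins, collagens with laminins and fibronectin, interferon-stimulated genes, antigen presentation, cytokines with chemokines and NF-kB targets, gp130 and STAT3 signalling, TGF-beta and BMP signalling, epithelial and mesenchymal genes, neural stem and progenitor genes, lysosome and lipid handling, glycolysis and hypoxia, complement, p53 targets, immediate early genes, ribosomal proteins, oxidative phosphorylation, and markers of microglia and macrophages, lymphocytes and granulocytes, oligodendrocytes, oligodendrocyte precursors, neurons, endothelium, fibroblasts and mural cells, ependyma, Schwann cells and erythrocytes.

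Named genes followed a fixed rule. Zeb2 and Zeb2os were named in every comparison, and Gfap, Vim, Lcn2, Serpina3n, Timp1 and Aqp4 in every astrocyte comparison. Added to these were the 6 largest rises and 6 largest falls among called genes with a mean log2 CPM of at least 3 and groups that did not overlap, without predicted models and small RNAs, and up to 4 called members of each list with the largest change, or up to 2 with the smallest p where none was called. Genes outside the rule were chosen after their values were seen, and are said to be. Groups, tests, gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. These alternatives were DESeq2 1.42.0, its size factors (RLE) inside edgeR, no expression filter, a filter at 1 CPM, the replicate number as a block, each library left out in turn and, for the sorted set, a fit of the compared pair of groups alone. Counts without Lars2 and Gm42418, counts thinned to equal totals (no other measure was matched, such as the share of detected genes with 1 to 3 counts, which ran from 1.62% to 12.9% in sorted libraries), fits across tables and sets of the 500 genes per direction with the smallest unadjusted p in the Zeb2 set were added after the data had been seen. Values of some genes that the rule for named genes selects are not reported here.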

Results

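The series asked how astrocytes of the mouse spinal cord change in the weeks and months after a contusion, and whether the long non-coding RNA Zeb2os, transcribed from inside the gene of the transcription factor Zeb2 on the opposite strand, takes part in their reaction. Gene counts came from cells sorted from the cord, labelled as astrocytes, of sham animals (34.0, 27.0 and 15.7 M counts in replicates 1 to 3) and of injured animals at 7 days (31.7, 36.8 and 44.0 M), 1 month (36.5, 50.2 and 34.4 M) and 3 months (36.3 and 22.5 M in replicates 1 and 3). Whole tissue at the injury site was sequenced at 1 and 3 months, at 15.4 to 27.1 M counts. Cultured astrocytes labelled Zeb2os knockdown (45.6 and 50.9 M) had 2 controls (78.8 and 158 M), and those labelled Zeb2 knockdown (42.8 and 29.0 M) had 2 controls of their own (65.4 and 50.2 M).

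Sorted libraries were set beside tissue, both 1 month after injury (3 libraries each), in a fit across both tables chosen after the data had been seen. With 1 estimate of spread per gene for both kinds, its SEs and p-values may be too small. Gfap, the filament protein of astrocytes, was lower in sorted cells than in tissue by a log2 difference of -5.29 ± 0.11 (SE), and the astrocyte water channel gene Aqp4 by -4.01 ± 0.16. Pdgfra, the receptor gene that marks oligodendrocyte precursors, was higher by 5.16 ± 0.11, Olig2, a transcription factor of the same lineage, by 3.62 ± 0.12, and Fos, which responds to stimulation within minutes, by 6.79 ± 0.16. All 14 precursor markers and 20 of 21 immediate early genes were higher in sorted cells, with median log2 differences of 3.87 and 4.23, while 23 of 25 genes of mature astrocyte function were lower (median -2.11). Camera gave adjusted p = 2.2e-13, 1.2e-15 and 1.7e-09 for these lists, and adjusted p = 0.0842, 0.0842 and 0.107 with an estimated correlation. The myelin gene Mbp and the synaptic gene Snap25 were lower in sorted cells by log2 differences of -5.97 ± 0.17 and -5.75 ± 0.19. C1qa, a microglia and complement gene, differed by -0.17 ± 0.19 (edgeR adjusted p = 0.484). The share of each cell type in the sort was not estimated, so sorted values are not those of astrocytes alone.

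**Figure D1:**
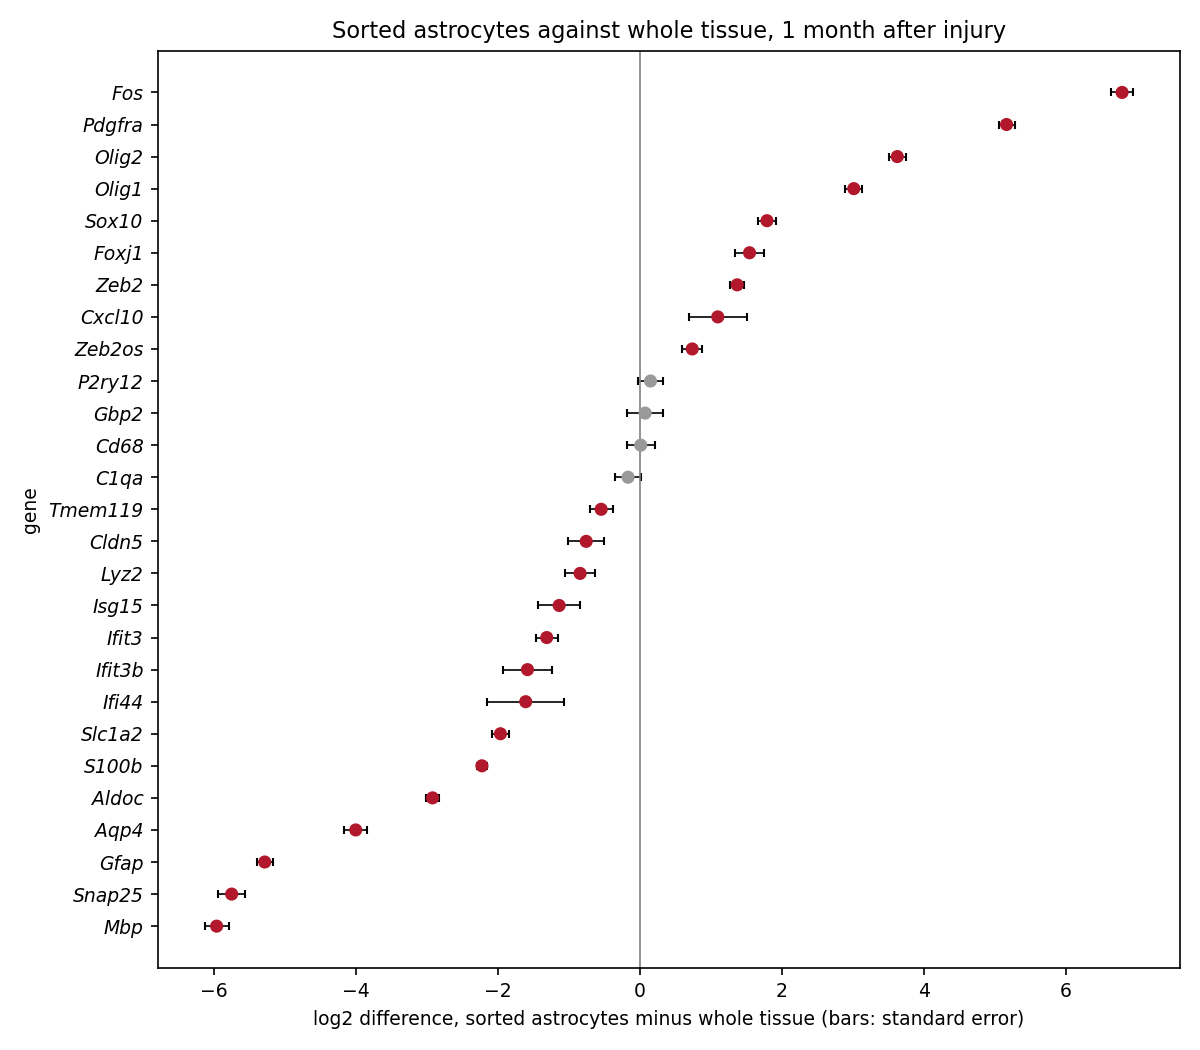
Log2 difference of marker genes between sorted cells and whole tissue at 1 month after injury (3 libraries each). Bars of 1 SE may be too short, and red points (edgeR adjusted p under 0.05) too many. Pdgfra (5.16) and Fos (6.79) lay to the higher side in sorted cells and Gfap (-5.29) and Mbp (-5.97) to the lower side.

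At 7 days after injury, 2398 genes rose and 2042 fell in sorted cells against sham among 24286 tested (3 libraries each), 1443 of the rises and 1432 of the falls by at least 2-fold. Without 7-day replicate 2 the number of calls was 2867, against 4440 with every library. Lars2 took 0.086% to 0.260% of counts in sham, 0.255% to 0.443% at 7 days, 0.083% to 0.142% at 1 month and 0.034% to 0.058% at 3 months. Gfap (chromosome 11, 102887336 to 102900912 in GRCm38) rose from 241 ± 100 to 1271 ± 155 CPM, a log2 change of 2.40 ± 0.25 (edgeR adjusted p = 9.4e-06). Serpina3n, a protease inhibitor gene of reactive astrocytes, rose from 39.6 ± 21.0 to 735 ± 92.1 CPM (log2 change 4.22 ± 0.35). Slc7a10, an amino acid transporter gene of astrocytes, fell from 346 ± 121 to 3.51 ± 0.594 CPM (log2 change -6.63 ± 0.28, edgeR adjusted p = 5e-09). Spp1, which encodes the secreted protein osteopontin, rose from 4.09 ± 1.76 to 1833 ± 491 CPM (log2 change 8.81 ± 0.40, edgeR adjusted p = 5.3e-09).

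Zeb2 rose from 191 ± 52.1 to 377 ± 77.7 CPM at 7 days (log2 change 0.98 ± 0.20, edgeR adjusted p = 0.0028). Counts assigned to Zeb2os rose from 13.2 ± 4.60 to 25.3 ± 1.77 CPM (log2 change 0.94 ± 0.25, edgeR adjusted p = 0.015). The value of Zeb2os is uncertain, since its exons overlap those of Zeb2 and the ratio of Zeb2os to Zeb2 CPM stayed between 0.060 and 0.0943 in all 11 sorted libraries. Its call was lost without 7-day replicate 1 (edgeR adjusted p = 0.0513) or replicate 2 (0.0601), and in a fit of the 2 groups alone (0.0576). Of the long non-coding genes, 115 rose and 226 fell among 7988 tested.

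Other genes with the largest rises were Gpnmb, a glycoprotein gene of phagocytes (log2 change 8.67 ± 0.69), Lyz2, the lysozyme gene of myeloid cells (6.25 ± 0.55), Col6a1, a chain of collagen VI (6.19 ± 0.57), Cybb, a subunit of the phagocyte oxidase (5.90 ± 0.51), and Postn, a matrix protein gene of fibroblasts (5.88 ± 0.89). The largest falls after Slc7a10 were Rph3a, a vesicle protein gene (-5.65 ± 0.32), Atp13a4, a transport ATPase gene (-5.59 ± 0.79), Gjb6, which encodes the astrocyte gap junction protein connexin 30 (-5.55 ± 0.47), Slc6a11, a GABA transporter gene (-5.52 ± 0.28), and Gpc5, a glypican gene (-4.90 ± 0.32). Vim, an intermediate filament gene, rose by a log2 change of 1.04 ± 0.31, and Timp1, an inhibitor of matrix proteases, by 4.00 ± 0.75. Aqp4 (chromosome 18, 15389496 to 15410982) fell from 528 ± 103 to 284 ± 97.8 CPM (edgeR adjusted p = 0.017), a call lost without sham replicate 2 (0.0597), 7-day replicate 2 (0.0537) or 7-day replicate 3 (0.0919). The call of Vim was lost without 7-day replicate 2 (0.0838) or replicate 3 (0.0924). A fit of the 2 groups alone called neither Vim (0.114) nor Aqp4 (0.0678). Lcn2, an iron-binding protein gene, had a log2 change of 1.89 ± 0.96 and was not called, but passed without sham replicate 2 (edgeR adjusted p = 0.0490).

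Of 25 genes of mature astrocyte function, 22 fell, none rose and 3 were not called at 7 days, and adjusted over the list alone 24 fell and 1 rose. This list kept its camera call (adjusted p = 1.4e-21) with an estimated correlation (adjusted p = 0.0193). Of 24 cholesterol synthesis genes, 19 fell (21 adjusted over the list alone), among them Tm7sf2 (log2 change -2.30 ± 0.31) and Msmo1 (-1.95 ± 0.22), with camera adjusted p = 1.5e-13, and adjusted p = 0.186 with an estimated correlation. Among cell cycle genes, 34 of 35 rose (all 35 adjusted over the list alone), with Ccnb1, a cyclin of mitosis, at a log2 change of 3.26 ± 0.41 and the topoisomerase Top2a at 3.02 ± 0.30. The median was 2.31, camera gave adjusted p = 3.7e-24, and adjusted p = 0.0584 with an estimated correlation. Of 13 pan-reactive astrocyte genes 7 rose, of 11 A1-type genes 8 rose and 1 fell, and of 12 A2-type genes 7 rose. Adjusted over the list alone, 7, 8 and 8 rose and 1 A1-type gene fell. The camera test gave adjusted p = 0.000202, 0.000609 and 0.000153, and adjusted p = 0.103, 0.228 and 0.103 with an estimated correlation. Srgn, a proteoglycan of secretory granules in the A1-type list, rose by 3.25 ± 0.39, while Amigo2, an adhesion molecule in that list, fell (-2.45 ± 0.48), and the prostaglandin synthase Ptgs2 of the A2-type list rose by 3.63 ± 0.47.

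Of 24 microglia and macrophage markers, 20 rose and 4 were not called at 7 days (21 higher and 1 lower adjusted over the list alone), with a median log2 change of 2.41. Cd68, a lysosomal protein of macrophages, rose by 3.85 ± 0.44, and C1qa from 98.5 ± 79.1 to 637 ± 92.5 CPM. Next to these markers, 21 of 24 lysosome and lipid handling genes rose, including the lipase gene Lpl (3.94 ± 0.35), and so did 17 of 28 cytokine, chemokine and NF-kB target genes, including Il1b (4.44 ± 0.82). In the cytokine list 3 genes fell, including Il6 (-3.05 ± 0.89), whose call was lost in 4 of the 6 fits that left out a library (highest edgeR adjusted p = 0.228). Of 16 complement genes 8 rose, including the receptor C3ar1 (3.23 ± 0.34). Adjusted over the list alone, 22 lysosome, 21 cytokine and 8 complement genes rose and 5 cytokine genes fell. Testing with camera gave adjusted p = 3.8e-12 for microglia, 2.1e-16 for lysosome, 4.7e-06 for cytokines and 0.000723 for complement, and adjusted p = 0.244, 0.186, 0.236 and 0.244 with an estimated correlation. Of 30 interferon-stimulated genes 8 rose (11 adjusted over the list alone), led by the chemokine Cxcl10 (3.13 ± 0.47), and of 17 antigen presentation genes 6 rose (7 higher and 1 lower adjusted over the list alone), such as B2m (1.32 ± 0.30). Camera returned adjusted p = 3.0e-05 and 0.00308, and adjusted p = 0.236 and 0.293 with an estimated correlation.

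All 15 endothelial markers rose at 7 days, as did 8 of 16 fibroblast and mural markers and 21 of 26 genes of collagens, laminins and fibronectin. Cdh5, the cadherin of vessel walls, rose by a log2 change of 3.24 ± 0.44 and the collagen gene Col1a1 from 55.7 ± 54.7 to 1202 ± 103 CPM. Adjusted over the list alone, 15, 8 and 22 rose and 0, 1 and 1 fell. The result from camera was adjusted p = 1.7e-10, 0.000490 and 6.6e-14, and adjusted p = 0.226, 0.226 and 0.103 with an estimated correlation. Of 14 ependymal markers 12 fell (12 adjusted over the list alone), led by Ccdc153 (-2.70 ± 0.30), with camera adjusted p = 3.3e-07, and adjusted p = 0.244 with an estimated correlation. Of 18 neuron markers 6 fell and 2 rose (7 and 2 adjusted over the list alone), with Gad1, which makes GABA, at -2.31 ± 0.34 and Snap25 at -2.23 ± 0.28. The neuron list had camera adjusted p = 0.0156, adjusted p = 0.244 with an estimated correlation, and adjusted p = 0.0809 without sham replicate 1. Oligodendrocyte precursor markers held a single call, a fall of Pdgfra from 2316 ± 300 to 1643 ± 179 CPM (none adjusted over the list alone, camera adjusted p = 0.303), which was lost in 4 of the 6 fits that left out a library (highest edgeR adjusted p = 0.228). Of 18 oligodendrocyte markers 3 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.0841), the tight junction gene Cldn11 by 4.06 ± 0.89. Schwann cell markers had 3 rises and 1 fall among 10 (3 and 1 adjusted over the list alone, camera adjusted p = 0.0794), with Gldn, a gliomedin gene, at 4.80 ± 0.74. None of 5 erythrocyte markers was called, by either adjustment (camera adjusted p = 0.0975). Among 15 lymphocyte and granulocyte markers 2 fell (2 adjusted over the list alone, camera adjusted p = 0.831). These were Elane and Mpo, neutrophil enzymes with no count in any 7-day library and 4.93 ± 7.85 and 3.55 ± 5.73 CPM in sham, and each lost its call in 3 of the fits that left out a library (highest edgeR adjusted p = 0.0857 and 0.0867).

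Immediate early genes moved the other way, with 14 of 21 lower at 7 days (15 lower and 1 higher adjusted over the list alone), among them the heat shock gene Hspa1b (-3.21 ± 0.31) and the growth regulator Btg2 (-2.32 ± 0.39). Camera gave adjusted p = 4.7e-08, and adjusted p = 0.244 with an estimated correlation. Of 81 ribosomal protein genes 54 rose (65 higher and 1 lower adjusted over the list alone), such as Rpl23 (1.42 ± 0.25), with camera adjusted p = 3.6e-15, and adjusted p = 0.342 with an estimated correlation. Of 76 oxidative phosphorylation genes 2 rose and 2 fell (none and 1 adjusted over the list alone, camera adjusted p = 0.443). Chondroitin sulfate proteoglycan and tenascin genes had 4 falls and 2 rises among 18 (6 and 2 adjusted over the list alone), with Bcan, the brevican gene, at -1.47 ± 0.21 and the tenascin gene Tnc at 3.07 ± 0.42. The camera test gave adjusted p = 0.0379 for a fall, and adjusted p = 0.334 with an estimated correlation. Of 22 glycolysis and hypoxia genes 5 fell and 2 rose (7 and 3 adjusted over the list alone), with Vegfa, the vessel growth factor gene, at -2.40 ± 0.18. Of 26 TGF-beta and BMP signalling genes 10 rose and 1 fell (10 and 4 adjusted over the list alone). Testing with camera gave adjusted p = 0.0251 and 0.0140 for these lists, and adjusted p = 0.505 and 0.293 with an estimated correlation. The call of the proteoglycan list was lost in 4 of the 6 fits that left out a library (highest camera adjusted p = 0.149), that of glycolysis without sham replicate 1 or 7-day replicate 1 (0.302) and that of TGF-beta without sham replicate 2 (0.0783).

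The remaining lists were not called by camera at 7 days. Of 18 gp130 and STAT3 signalling genes 5 rose and 3 fell (6 and 3 adjusted over the list alone, camera adjusted p = 0.150), with the receptor Osmr at 3.26 ± 0.55 and the receptor Cntfr at -1.61 ± 0.16. Of 17 p53 targets 4 rose and 3 fell (7 and 3 adjusted over the list alone, camera adjusted p = 0.303), with Pmaip1, a promoter of cell death, at 1.64 ± 0.36. Of 15 neural stem and progenitor genes 3 rose and 6 fell (6 and 7 adjusted over the list alone, camera adjusted p = 0.671), with the filament gene Nes at 2.21 ± 0.20 and the transcription factor gene Sox9 at -2.05 ± 0.39. Its median log2 change was 0.06 and its mean -0.34. Among 17 epithelial and mesenchymal genes only Twist1, at 2.03 ± 0.342 CPM, rose (1 adjusted over the list alone, camera adjusted p = 0.159), and the list had a median of -0.18 and a mean of 0.71.

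**Figure D2:**
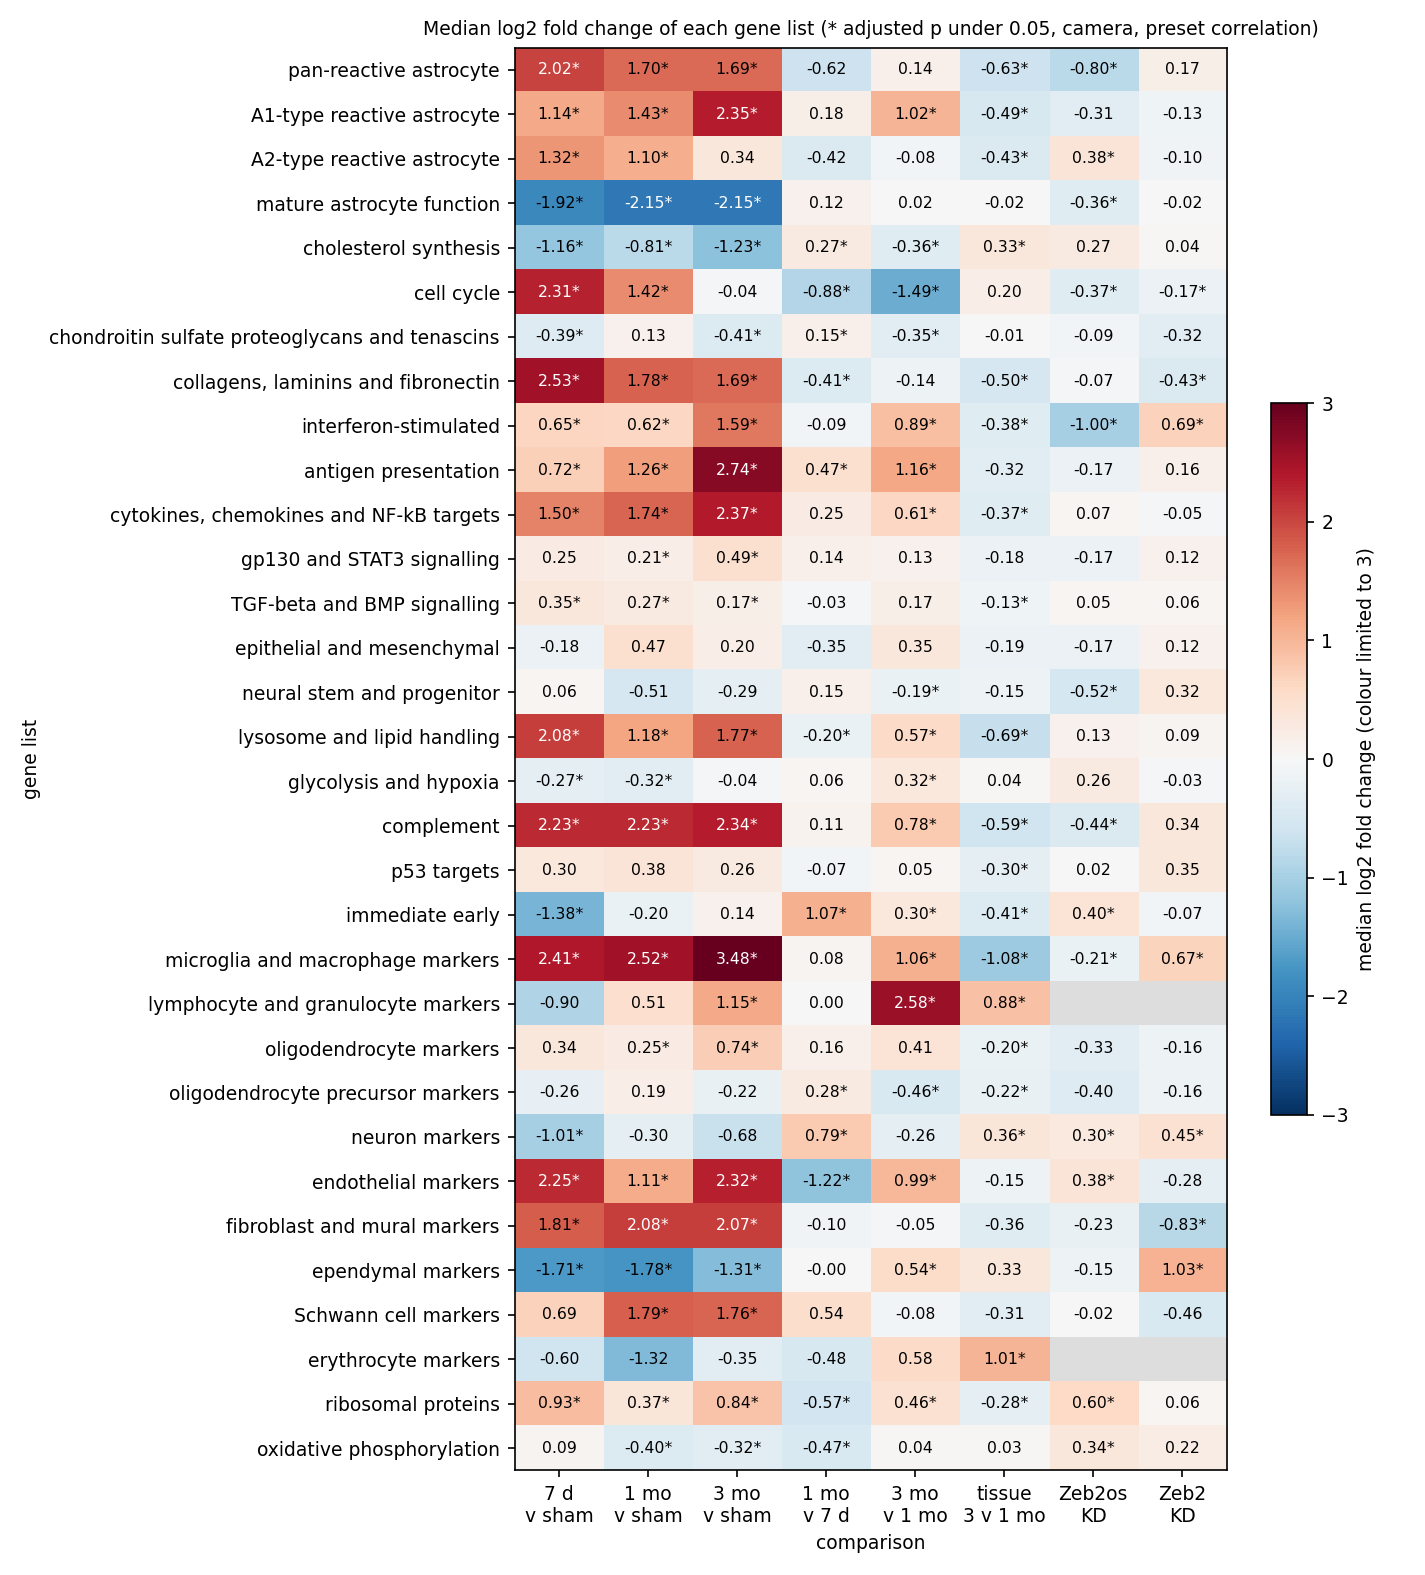
Median log2 change of each of the 32 gene lists (rows) in the 8 comparisons (columns), with an asterisk for a camera adjusted p under 0.05 and grey for a list not tested. Cell cycle genes had medians of 2.31 at 7 days and 1.42 at 1 month against sham.

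At 1 month after injury, 1512 genes rose and 1415 fell against sham (3 libraries each), 1049 and 1042 of them by at least 2-fold. Gfap was at 233 ± 33.4 CPM, with a log2 change of -0.05 ± 0.23 against sham (edgeR adjusted p = 0.94). Serpina3n rose to 165 ± 7.21 CPM (log2 change 2.07 ± 0.32) and Timp1 by 3.17 ± 0.72 (edgeR adjusted p = 0.0815 in a fit of the 2 groups alone), while Vim (0.37 ± 0.31) and Lcn2 (1.70 ± 0.95) were not called. Aqp4 fell to 75.7 ± 12.6 CPM (log2 change -2.80 ± 0.26, edgeR adjusted p = 7.5e-06).

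Zeb2 rose to 377 ± 8.07 CPM at 1 month (log2 change 0.98 ± 0.20, edgeR adjusted p = 0.0045) and the counts assigned to Zeb2os to 26.7 ± 3.79 CPM (1.02 ± 0.25, edgeR adjusted p = 0.014). The Zeb2os call was lost without 1-month replicate 2 (0.0539) or replicate 3 (0.0668), and in a fit of the 2 groups alone (0.0610). The largest rises were Gpnmb (8.49 ± 0.68), Spp1 (8.27 ± 0.39), Postn (6.01 ± 0.90), Cybb (6.00 ± 0.51), Itgax, an integrin gene of dendritic cells and activated microglia (5.95 ± 0.83), and Col6a1 (5.81 ± 0.56). The largest falls were Hsd11b1, which activates glucocorticoids (-5.54 ± 0.42), Slc7a10 (-5.10 ± 0.26), Itih3, a hyaluronan-binding protein gene (-4.93 ± 0.34), Grin2c, a glutamate receptor subunit gene (-4.91 ± 0.66), Car14, a carbonic anhydrase gene (-4.62 ± 0.50), and Gjb6 (-4.48 ± 0.44). Of the long non-coding genes, 110 rose and 138 fell. Without 1-month replicate 3 the number of calls was 1727 and without replicate 2 it was 1806, against 2927 with every library. Falls outnumbered rises without sham replicate 2 (1382 rises and 1554 falls) and in a fit of the 2 groups alone (935 and 1024), while without sham replicate 1 rises made up 62.1% of calls (2154 and 1317) against 51.7%.

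Mature astrocyte function genes had 22 falls among 25 at 1 month (23 adjusted over the list alone, median -2.15), including Aldh1l1, a folate enzyme of astrocytes (-3.40 ± 0.35). Camera returned adjusted p = 1.7e-25, and adjusted p = 0.0112 with an estimated correlation. Microglia and macrophage markers had 20 rises among 24 (21 adjusted over the list alone, median 2.52), with Lyz2 at 5.12 ± 0.52, Cd68 at 4.38 ± 0.46 and C1qa at 849 ± 204 CPM. Beside them, 17 of 24 lysosome and lipid handling genes rose, such as the protease gene Ctsd (3.20 ± 0.36), and 17 of 28 cytokine, chemokine and NF-kB target genes rose and 3 fell, with Il1b at 4.88 ± 0.84 and the NF-kB inhibitor Tnfaip3 at 3.27 ± 0.35. Of 17 antigen presentation genes 10 rose, including B2m (2.02 ± 0.30) and Cd74 (1.85 ± 0.35). Adjusted over the list alone, 18 lysosome, 19 cytokine and 13 antigen presentation genes rose and 4 cytokine genes fell. The result from camera was adjusted p = 2.9e-14, 2.9e-14, 3.3e-08 and 9.2e-08 in this order, and adjusted p = 0.188, 0.176, 0.176 and 0.176 with an estimated correlation.

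Cell cycle genes had 31 rises among 35 at 1 month (33 adjusted over the list alone), with Top2a at 2.15 ± 0.29 and Mki67, a marker of dividing cells, at 2.12 ± 0.24. Camera gave adjusted p = 4.2e-20, and adjusted p = 0.0976 with an estimated correlation. Of 24 cholesterol synthesis genes 13 fell (21 adjusted over the list alone), with camera adjusted p = 2.5e-10, and adjusted p = 0.179 with an estimated correlation. Ependymal markers had 13 falls among 14 (13 adjusted over the list alone), such as Pifo, a gene of cilia (-2.27 ± 0.38). Endothelial markers had 8 rises among 15 (9 adjusted over the list alone), such as the growth factor receptor Flt1 (1.94 ± 0.32), and Schwann cell markers 5 rises and 1 fall among 10 (5 and 1 adjusted over the list alone), such as Gldn (4.49 ± 0.73). The camera test gave adjusted p = 8.8e-09, 2.2e-06 and 0.000999, and adjusted p = 0.188, 0.266 and 0.188 with an estimated correlation.

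Calls of the 7-day and 1-month comparisons overlapped in 2264 genes called in the same direction (1231 higher, 1033 lower), and 4 genes were called in opposite directions. Independent lists of these sizes would share 149 and 119. In simulations of unchanged groups against the same sham libraries, no call was shared in 20 runs. Log2 changes across genes correlated at 0.677 against 0.166 in the simulations, with a covariance of 2.40 against 0.178. At 1 and 3 months, 1803 genes were shared (1047 higher, 756 lower, 0 opposite), where independent lists would share 102 and 69.8. The covariance there was 2.66 against 0.236 in the simulations. The 3 sham libraries could not be split into parts of at least 2, so part of each excess may come from the shared controls.

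At 3 months after injury, in 2 libraries against the 3 of sham, 1646 genes rose and 1198 fell, 1303 and 824 of them by at least 2-fold. The lipid carrier Apoe rose from 2071 ± 405 to 34760 ± 7290 CPM (log2 change 4.07 ± 0.26). Cd74, the invariant chain of MHC class II, rose from 32.5 ± 21.4 to 674 ± 169 CPM (4.38 ± 0.40). Aqp4 fell to 54.7 ± 12.1 CPM (-3.27 ± 0.31, edgeR adjusted p = 6.4e-06). Gfap was at 172 ± 6.26 CPM (-0.48 ± 0.26, edgeR adjusted p = 0.27), and Vim (0.86 ± 0.34) and Lcn2 (2.90 ± 1.04) were not called by edgeR either. Vim and Lcn2 were called by DESeq2 (adjusted p = 0.0366 and 0.0205) and by edgeR without an expression filter (0.00373 and 0.0113). Vim was also called without sham replicate 3 (0.0496) and Lcn2 without sham replicate 2 (0.0256). Serpina3n (1.94 ± 0.34) and Timp1 (2.96 ± 0.76) rose, the latter not without 3-month replicate 3 (edgeR adjusted p = 0.214) or in a fit of the 2 groups alone (0.275).

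Zeb2 rose to 366 ± 2.50 CPM at 3 months (log2 change 0.94 ± 0.22, edgeR adjusted p = 0.011) and the counts assigned to Zeb2os to 32.9 ± 2.06 CPM (1.32 ± 0.28, edgeR adjusted p = 0.0048). The Zeb2 call was lost without 3-month replicate 1 (0.0547) or replicate 3 (0.0767), and in a fit of the 2 groups alone those of Zeb2 (0.103) and Zeb2os (0.0825) were. The largest rises were Gpnmb (9.72 ± 0.72), Spp1 (8.83 ± 0.40), Cybb (7.40 ± 0.55), Lyz2 (6.57 ± 0.57), Cd68 (5.51 ± 0.49) and Ly9, a receptor gene of lymphocytes (5.29 ± 0.40). The largest falls were Grin2c (-5.81 ± 0.84), Etnppl, an enzyme gene of lipid metabolism (-5.48 ± 0.68), Atp13a4 (-4.82 ± 0.91), Itih3 (-4.80 ± 0.40), Slc7a10 (-4.58 ± 0.30) and the fatty acid elongase gene Elovl2 (-4.00 ± 0.43). Without 3-month replicate 3 the number of calls was 1189, against 2844. Its 859 rises and 330 falls made a share of rises of 72.2% against 57.9%. A fit of the 2 groups alone had 665 and 220 (75.1%).

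Of 17 antigen presentation genes 15 rose at 3 months (16 adjusted over the list alone, median 2.74), including the MHC class II genes H2-Eb1 (3.93 ± 0.36), H2-Aa (3.74 ± 0.44) and H2-Ab1 (3.73 ± 0.29). Of 30 interferon-stimulated genes 16 rose (22 adjusted over the list alone), with Cxcl10 at 4.39 ± 0.52 and the GTPase gene Iigp1 at 4.10 ± 0.51. Beside these lists, 21 of 24 microglia and macrophage markers rose (22 adjusted over the list alone, median 3.48), with C1qa at 1956 ± 599 CPM. Testing with camera gave adjusted p = 1.5e-15, 4.4e-11 and 6.9e-20, and adjusted p = 0.0824, 0.122 and 0.138 with an estimated correlation. Of 28 cytokine, chemokine and NF-kB target genes 20 rose and 2 fell (20 and 3 adjusted over the list alone), with Il1b at 5.11 ± 0.87, and of 24 lysosome and lipid handling genes 20 rose and 1 fell (22 and 1 adjusted over the list alone), with Lpl at 5.21 ± 0.38. Camera returned adjusted p = 7.8e-12 and 1.0e-17, and adjusted p = 0.122 for both with an estimated correlation.

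Mature astrocyte function genes had 22 falls among 25 at 3 months (22 adjusted over the list alone), with camera adjusted p = 1.7e-21, and adjusted p = 0.0188 with an estimated correlation. Cholesterol synthesis genes had 19 falls among 24 (20 adjusted over the list alone), with camera adjusted p = 5.6e-13, and adjusted p = 0.129 with an estimated correlation. The cell cycle list held a single call, a rise of Mcm3, a DNA replication factor (1.10 ± 0.24, 1 adjusted over the list alone, camera adjusted p = 0.610), and it was lost in 1 of the 5 fits that left out a library (edgeR adjusted p = 0.255). Its median of -0.04 and mean of 0.01 differed in sign. Ependymal markers had 6 falls among 14 (13 adjusted over the list alone), and endothelial markers 14 rises among 15 (14 adjusted over the list alone). The result from camera was adjusted p = 5.4e-05 and 1.1e-10, and adjusted p = 0.359 and 0.154 with an estimated correlation.

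**Figure D3:**
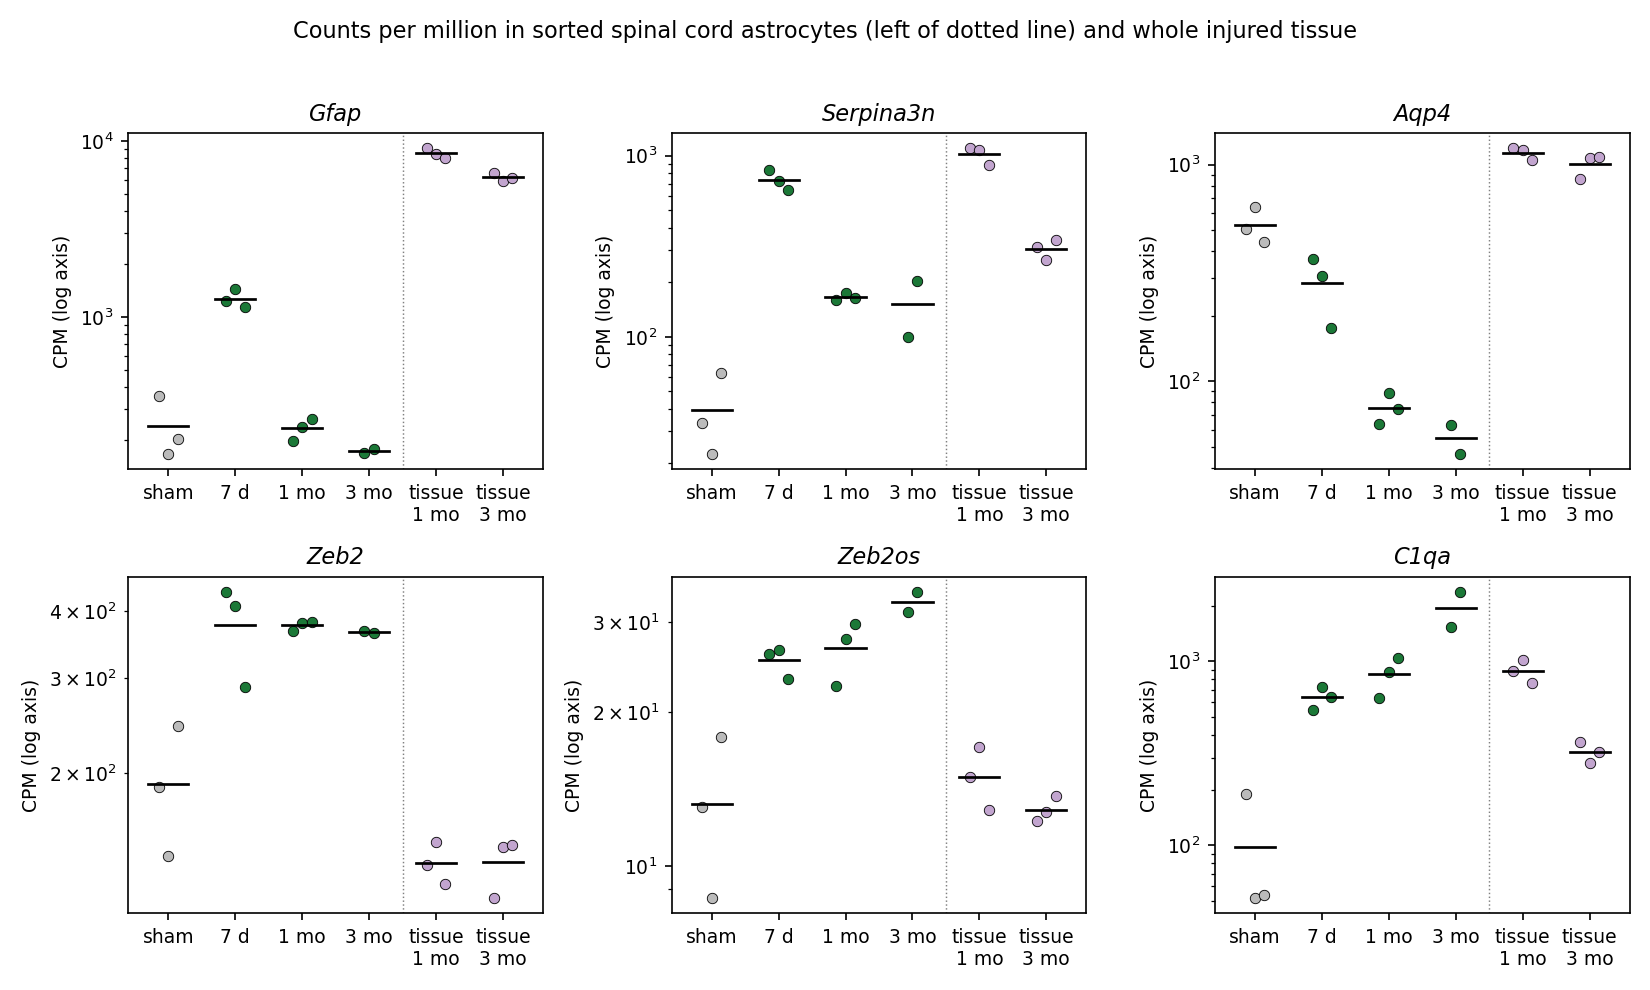
CPM on a log axis of Gfap, Serpina3n, Aqp4, Zeb2, Zeb2os and C1qa in each sorted library (left of the dotted line) and tissue library (right), with lines at group means. Gfap had a mean of 1271 CPM at 7 days and 233 at 1 month, while Zeb2 stayed at 377 in both.

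Between 7 days and 1 month in sorted cells, 368 genes rose and 265 fell. Gfap fell from 1271 ± 155 to 233 ± 33.4 CPM (log2 change -2.45 ± 0.25, edgeR adjusted p = 0.00034, 3 libraries each), Serpina3n by a log2 change of -2.15 ± 0.32 and Aqp4 by -1.91 ± 0.25. Zeb2 (0.00 ± 0.20), Zeb2os (0.08 ± 0.25), Vim (-0.67 ± 0.31), Lcn2 (-0.19 ± 0.92) and Timp1 (-0.82 ± 0.65) were not called. In a fit of the 2 groups alone Vim (edgeR adjusted p = 0.000267) and Timp1 (0.0430) were, and so was Vim without an expression filter (0.0352). Immediate early genes had 8 rises among 21 (15 adjusted over the list alone), with Fosb from 784 ± 23.8 to 2550 ± 386 CPM, Egr1 from 1201 ± 79.7 to 3400 ± 306 CPM and Klf4 at 1.54 ± 0.24.

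The largest rises from 7 days to 1 month were Ptgds, a prostaglandin synthase gene (log2 change 5.40 ± 1.16), the macrophage elastase gene Mmp12 (3.07 ± 0.46), Itgax (2.86 ± 0.71), the matrix gene Fmod (2.61 ± 0.35), the neuronal activity gene Arc (2.53 ± 0.36) and the circadian repressor gene Ciart (2.46 ± 0.47). The largest falls were Col2a1, a cartilage collagen gene (-3.77 ± 0.49), the fatty acid receptor gene Cd36 (-3.60 ± 0.57), the lipase inhibitor gene Angptl4 (-3.15 ± 0.35), the basement membrane gene Col4a6 (from 56.4 ± 6.30 to 7.03 ± 2.59 CPM), Cd93, a surface receptor gene of endothelium and myeloid cells (-2.96 ± 0.34), and the channel subunit gene Kcne1l (-2.61 ± 0.45). Cell cycle genes had 8 falls among 35 (22 adjusted over the list alone), such as Ccnb2 (-1.76 ± 0.43), and endothelial markers 4 falls among 15 (11 adjusted over the list alone), such as Cldn5 (-2.01 ± 0.38). Camera gave adjusted p = 1.4e-12 for immediate early genes, 3.8e-10 for cell cycle and 2.6e-06 for endothelium, and adjusted p = 0.615 for each with an estimated correlation. None of 24 microglia and macrophage markers was called, by either adjustment (camera adjusted p = 0.999), and their median of 0.08 and mean of -0.01 differed in sign. The calls of Ptgds, Itgax, Col4a6 and Ccnb2 were lost in each of the 6 fits that left out a library (highest edgeR adjusted p = 0.124, 0.189, 0.113 and 0.185), and those of Ciart and Cldn5 in 3 and 5 of them. The number of calls ran from 122 (without 7-day replicate 2) to 218 (without 7-day replicate 3) in these 6 fits, against 633. In a fit of the 2 groups alone there were 1720 rises and 1840 falls, a share of rises of 48.3% against 58.1%, while the 6 fits that left out a library had 68.0% to 76.7%.

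Between 1 and 3 months in sorted cells, 25 genes rose and 69 fell. The MHC class II gene H2-Ab1 rose from 30.1 ± 8.87 to 181 ± 39.2 CPM (log2 change 2.59 ± 0.28, edgeR adjusted p = 0.0015, 3 libraries against 2), H2-Aa by 2.77 ± 0.42, H2-Eb1 by 2.67 ± 0.34 and Cd74 by 2.53 ± 0.38. The mitotic genes Kif2c (-2.41 ± 0.33), Dlgap5 (-2.24 ± 0.46), Spag5 (-2.23 ± 0.34), Kifc1 (-2.19 ± 0.35) and Troap (-2.15 ± 0.43) were among the largest falls. Cenpf, a centromere protein gene, fell from 69.7 ± 3.57 to 16.8 ± 4.80 CPM. Zeb2 (-0.04 ± 0.23), Zeb2os (0.30 ± 0.28), Gfap (-0.43 ± 0.26), Aqp4 (-0.47 ± 0.28), Vim (0.49 ± 0.34), Lcn2 (1.20 ± 1.01), Serpina3n (-0.13 ± 0.34) and Timp1 (-0.21 ± 0.73) were not called. Vim was called in a fit of the 2 groups alone (edgeR adjusted p = 0.0146).

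Cell cycle genes had 15 falls among 35 from 1 to 3 months (31 adjusted over the list alone, median -1.49), and antigen presentation genes 7 rises among 17 (13 adjusted over the list alone, median 1.16). The camera test gave adjusted p = 1.2e-28 and 5.1e-13, and adjusted p = 0.0735 and 0.124 with an estimated correlation. Beside them, no microglia and macrophage marker was called among 24 (2 rose adjusted over the list alone), though the list had a median of 1.06 and camera adjusted p = 2.9e-08, and adjusted p = 0.510 with an estimated correlation. Interferon-stimulated genes had 1 rise, of the GTPase gene Gbp2 (1.42 ± 0.29), among 30 (1 adjusted over the list alone, median 0.89), with camera adjusted p = 8.9e-06, and adjusted p = 0.368 with an estimated correlation. Of the remaining largest rises, Atp6v0d2 (2.16 ± 0.27) encodes a proton pump subunit and Anpep (2.08 ± 0.39) an aminopeptidase, and Apoe rose by 1.31 ± 0.24. DESeq2 called 249 rises and 401 falls, so the share of rises was 38.3% against 26.6% in edgeR, and edgeR with RLE scaling called 29 and 55 (34.5%). Falls did not outnumber rises without an expression filter (411 rises and 338 falls, 54.9% rises), in a fit of the 2 groups alone (644 and 633, 50.4%) or without 3-month replicate 3 (5 and 2, 71.4%). The number of calls ran from 7 (without 3-month replicate 3) to 52 (without 3-month replicate 1) in the 5 fits that left out a library, against 94. Of the genes named above, H2-Ab1 and H2-Eb1 kept their calls without any single library, while Cd74 and Gbp2 lost theirs in 4 of the 5 fits (highest edgeR adjusted p = 0.0805 and 0.528), H2-Aa and Spag5 in 2 (0.123 for Spag5), and Kif2c, Cenpf and Atp6v0d2 in 1 (0.0675 for Cenpf and 0.0539 for Atp6v0d2). The calls of Dlgap5, Kifc1, Troap, Anpep and Apoe were lost in each of the 5 (highest edgeR adjusted p = 0.321, 0.103, 0.222, 0.198 and 0.372).

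In whole tissue from 1 to 3 months, 1315 genes rose and 1574 fell among 19652 tested (3 libraries each), 225 and 262 of them by at least 2-fold. Serpina3n fell from 1020 ± 111 to 307 ± 38.8 CPM (log2 change -1.73 ± 0.12, edgeR adjusted p = 0.0020), C1qa from 888 ± 127 to 322 ± 43.1 CPM (-1.46 ± 0.13) and the lysosomal protease gene Ctsd from 3126 ± 366 to 841 ± 147 CPM (-1.89 ± 0.15). The glutamate transporter gene of neurons, Slc17a6, rose from 85.6 ± 8.50 to 140 ± 17.8 CPM (0.71 ± 0.11), a call lost without 1-month tissue replicate 1 or replicate 2 (highest edgeR adjusted p = 0.0639). Zeb2 was at 136 ± 12.2 CPM at 1 month and 137 ± 16.8 at 3 months (0.01 ± 0.11), and Zeb2os at 14.9 ± 2.11 and 12.9 ± 0.761 CPM (-0.21 ± 0.12, edgeR adjusted p = 0.28). Neither was called.

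The largest falls in tissue were Cd5l, a macrophage protein gene (-3.65 ± 0.27), Ch25h, a cholesterol hydroxylase gene (-2.60 ± 0.13), the matrix protease gene Mmp3 (-2.44 ± 0.20), Lars2 (-2.42 ± 0.36), the chemokine gene Ccl3 (-2.31 ± 0.17) and the protease inhibitor gene Cst7 (-2.26 ± 0.18). The largest rises were the sensory neuron genes Scn10a (5.16 ± 0.96) and Pirt (4.19 ± 0.81), Tusc5 (4.46 ± 0.84) and the neutrophil genes Ltf (4.12 ± 1.02), Chil3 (4.06 ± 1.00) and Ngp (4.00 ± 1.00). Spread at 3 months was wide, with Scn10a at 120 ± 107 CPM and Ltf at 187 ± 244 CPM, and the calls of these 6 genes were lost without 1-month tissue replicate 1 or replicate 2 (highest edgeR adjusted p = 0.0786 for Scn10a and 0.145 for Ltf). All but Scn10a lost theirs in a further fit, Pirt without 3-month tissue replicate 3 and the others without 1-month tissue replicate 3. Lars2 was not called without 1-month tissue replicate 1 (edgeR adjusted p = 0.0557). Shares of all counts for Lars2 and Gm42418, tracked as a measure of library quality, were 0.103% to 0.127% and 0.052% to 0.066% at 1 month, and 0.013% to 0.035% and 0.007% to 0.015% at 3 months. Microglia and macrophage markers had 20 falls among 24 (23 adjusted over the list alone, median -1.08), such as Cd68 (-1.70 ± 0.15) and Trem2, a lipid receptor gene of microglia (-1.64 ± 0.15). Beside them, 18 of 24 lysosome and lipid handling genes fell (20 lower and 1 higher adjusted over the list alone), with Spp1 at -1.62 ± 0.14 and Gpnmb at -1.62 ± 0.15, and 10 of 27 cytokine, chemokine and NF-kB target genes (14 adjusted over the list alone), with the chemokine gene Ccl4 at -2.50 ± 0.17. Testing with camera gave adjusted p = 2.4e-15, 7.4e-12 and 3.6e-06, and adjusted p = 0.567 for each with an estimated correlation.

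Pan-reactive astrocyte genes had 7 falls among 13 in tissue (8 adjusted over the list alone), including Timp1 (-1.68 ± 0.16), and complement genes 6 falls among 15 (10 lower and 1 higher adjusted over the list alone), with C1qc at -1.65 ± 0.14. Camera returned adjusted p = 4.2e-06 and 4.9e-05, and adjusted p = 0.567 for both with an estimated correlation. Ribosomal protein genes had 42 falls among 80 (64 adjusted over the list alone, median -0.28), with camera adjusted p = 2.8e-15, and adjusted p = 0.600 with an estimated correlation. Neuron markers had 6 rises among 19 (12 adjusted over the list alone), such as the neurofilament gene Nefl (0.56 ± 0.10), and cholesterol synthesis genes 5 rises among 23 (11 adjusted over the list alone), such as Hmgcs1 (0.46 ± 0.10). Lymphocyte and granulocyte markers had 6 rises among 19 (9 adjusted over the list alone), such as S100a8 (3.83 ± 0.92), and erythrocyte markers 3 among 7 (4 adjusted over the list alone). The calls of Nefl, Hmgcs1 and S100a8 were lost in 2, 3 and 3 of the 6 fits that left out a library (highest edgeR adjusted p = 0.0838, 0.121 and 0.136). The result from camera was adjusted p = 1.4e-05, 3.0e-05, 0.000641 and 0.00600, and adjusted p = 0.567, 0.600, 0.600 and 0.600 with an estimated correlation. The erythrocyte call was lost without 3-month tissue replicate 1 (camera adjusted p = 0.0779). Mature astrocyte genes had 6 falls among 25 (7 adjusted over the list alone, camera adjusted p = 0.120), and no cell cycle gene was called among 35, by either adjustment (camera adjusted p = 0.244). The number of calls was 305, 573 and 1478 without 1-month tissue replicate 1, 2 or 3, and 5980, 1877 and 734 without 3-month tissue replicate 1, 2 or 3, against 2889. The share of rises, 45.5% with every library, ran from 22.3% without 1-month tissue replicate 1 (68 rises and 237 falls) to 52.1% without 3-month tissue replicate 2 (978 and 899), with 31.9% without 1-month tissue replicate 2. Rises also outnumbered falls by DESeq2 (1687 and 1675) and without an expression filter (1486 and 1384).

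Genes called in the tissue comparison, up to the 500 of smallest p per direction, were tested as sets in sorted cells over the same interval. Tissue risers had a median log2 change of -0.24 in sorted cells (camera adjusted p = 2.8e-06) and tissue fallers one of 0.38 (camera adjusted p = 6.4e-09). With an estimated correlation these were adjusted p = 0.0755 and 0.136.

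In cultures labelled Zeb2os knockdown, counts assigned to Zeb2os were 5.82 and 3.80 CPM in the controls and 3.14 and 4.32 CPM in the libraries labelled knockdown. The log2 change was -0.36 ± 0.35 (edgeR adjusted p = 0.73, 2 libraries each), with a 95% interval of -1.16 to 0.43. The values thus do not show the label's lower Zeb2os, and part of the counts cannot be told from reads of Zeb2, which was at 61.0 ± 13.0 CPM in controls and 53.7 ± 5.32 CPM in knockdown libraries (log2 change -0.18 ± 0.22, not called). Between these libraries, 25 genes were higher and 14 lower among 20741 tested, all by at least 2-fold. The number of calls was 4354 and 901 without control replicate 1 or 2, and 20 and 70 without knockdown replicate 1 or 2, against 39 with every library. Lars2 took 2.40% of the counts of knockdown replicate 1, against 0.066% to 0.168% in the other libraries of the set. Gfap fell from 518 ± 1.53 to 177 ± 23.8 CPM in the libraries labelled Zeb2os knockdown (log2 change -1.55 ± 0.23, edgeR adjusted p = 0.043). Serpina3n (-1.30 ± 0.21, edgeR adjusted p = 0.054), Aqp4 (-1.09 ± 0.24), Timp1 (1.20 ± 0.30), Vim (0.21 ± 0.24) and Lcn2 (-0.50 ± 0.51) were not called.

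The largest rises in the libraries labelled Zeb2os knockdown were Stmn3, a microtubule regulator gene (log2 change 2.84 ± 0.32), Crct1 (2.79 ± 0.33), the muscle filament gene Des (2.44 ± 0.30), the cytokine gene Il11 (2.28 ± 0.23), the transcription factor gene Klf2 (2.26 ± 0.24) and the retinoic acid binding gene Crabp2 (2.07 ± 0.31). The largest falls were Rab11fip4, a vesicle transport gene (-1.94 ± 0.24), Cxcl10 (-1.86 ± 0.25), the adhesion gene Igsf11 (-1.84 ± 0.23), the GTPase gene Gbp3 (-1.81 ± 0.20), the transporter gene Slc22a23 (-1.71 ± 0.23) and the RNA helicase gene Ddx60 (-1.69 ± 0.25). Of 30 interferon-stimulated genes 5 fell (23 adjusted over the list alone, median -1), including Ifi44 (-1.60 ± 0.20), Ifit3b (-1.60 ± 0.23) and Cxcl10, with camera adjusted p = 9.5e-15, and adjusted p = 0.342 with an estimated correlation. Ribosomal protein genes had no call among 81, by either adjustment, and a median of 0.60, with camera adjusted p = 2.6e-12, and adjusted p = 0.666 with an estimated correlation. The ribosomal median was 1.17 without control replicate 1 and 0.21 without control replicate 2. No cell cycle gene was called among 35 (13 fell adjusted over the list alone), and no mature astrocyte gene among 25 (10 fell adjusted over the list alone). Camera gave adjusted p = 3.7e-05 and 0.00106, and adjusted p = 0.429 for both with an estimated correlation. The mature astrocyte call was lost without knockdown replicate 2 (0.165). Of 13 pan-reactive genes 2 fell, Gfap and Cxcl10 (6 lower and 3 higher adjusted over the list alone), with camera adjusted p = 0.0141, and adjusted p = 0.429 with an estimated correlation. This call was lost in each of the 4 fits that left out a library (camera adjusted p = 0.0667 to 0.209). DESeq2 called 265 rises and 288 falls, a share of rises of 47.9% against 64.1% in edgeR, and edgeR without an expression filter 258 and 367 (41.3%). Without knockdown replicate 1 edgeR called 19 rises and 1 fall (95%), and the other fits that left out a library had 53.6% to 54.3% rises. Gfap was not called without knockdown replicate 1 (edgeR adjusted p = 0.228) or replicate 2 (0.236), nor Rab11fip4, Cxcl10, Igsf11 and Gbp3 without knockdown replicate 1. Slc22a23, Ddx60, Ifi44 and Ifit3b were called neither without knockdown replicate 1 nor without replicate 2 (highest edgeR adjusted p = 0.182, 0.121, 0.192 and 0.175). Serpina3n, Timp1 and Aqp4 were called by DESeq2 (adjusted p = 1.27e-05, 0.00173 and 0.00186), and by edgeR without an expression filter or without control replicate 1 or 2. Serpina3n was also called with the filter at 1 CPM (edgeR adjusted p = 0.0445). Vim was called without control replicate 1 (edgeR adjusted p = 0.0449).

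In cultures of the Zeb2 set, Zeb2 was at 147 and 134 CPM in the controls and at 23.2 and 16.1 CPM in the libraries labelled Zeb2 knockdown, a log2 change of -2.83 ± 0.33 (2 libraries each). No gene was called by edgeR among 17609 tested, Zeb2 included, and the smallest adjusted p was 0.999. At an unadjusted p under 0.05 edgeR gave 683 genes (273 higher, 410 lower), and DESeq2 called 32. Without an expression filter edgeR called 142, without control replicate 1 or 2 it called 17 and 4, and without knockdown replicate 1 or 2 it called 2 and 804. Zeb2 was called by DESeq2 (adjusted p = 1.1e-08), by edgeR with no expression filter (4.2e-08) and by edgeR without control replicate 1 (0.0427), knockdown replicate 1 (0.0406) or knockdown replicate 2 (0.0211). Counts assigned to Zeb2os were at 5.02 ± 1.38 CPM in controls and 3.52 ± 0.260 CPM in knockdown libraries (-0.52 ± 0.43). Log2 changes of the other fixed genes were 0.27 ± 0.39 for Gfap, -0.65 ± 0.39 for Aqp4, 0.25 ± 0.44 for Vim, 0.26 ± 1.14 for Serpina3n, -0.81 ± 0.78 for Timp1 and 0.93 ± 2.51 for Lcn2. Timp1 was called without knockdown replicate 2 (-2.57) and Lcn2 without control replicate 1 (14.7).

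No member of any list was called by edgeR in the Zeb2 set, by either adjustment, with every library, the expression filter and no replicate block. Among the genes that the rule for named genes selects there, Zeb2 included, DESeq2 called 2 and edgeR without a filter 9. Without control replicate 1 or 2 edgeR called 3 and 0 of them, and without knockdown replicate 1 or 2 it called 1 and 16. The camera test gave adjusted p = 5.7e-07 for 29 interferon-stimulated genes (median 0.69), with Rsad2, an antiviral enzyme gene, at 2.63 ± 0.71 and Ifi44 at 2.03 ± 0.67, and adjusted p = 6.5e-07 for 10 ependymal markers (median 1.04), with the cilia regulator Foxj1 at 0.84 ± 0.29. With an estimated correlation these were adjusted p = 0.890 for both. Without knockdown replicate 1 the interferon median was 0.34. Genes of collagens, laminins and fibronectin had a median of -0.43 over 26 tested, with Col4a1 at -1.13 ± 0.35, and camera adjusted p = 0.00525, and adjusted p = 0.990 with an estimated correlation. Without control replicate 1 this median was 0.01 and without knockdown replicate 1 it was -0.83. The call was lost without control replicate 1 or knockdown replicate 2 (highest camera adjusted p = 0.721). Microglia and macrophage markers had a median of 0.67 over 21 tested, with C1qa at 1.55 ± 1.47 CPM in controls and 3.08 ± 2.67 CPM in knockdown libraries, with camera adjusted p = 0.0361, and adjusted p = 0.990 with an estimated correlation. Without knockdown replicate 1 the microglia median was -0.35 and without control replicate 1 it was 2.06. The call was lost without control replicate 2 or knockdown replicate 1.

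**Figure D4:**
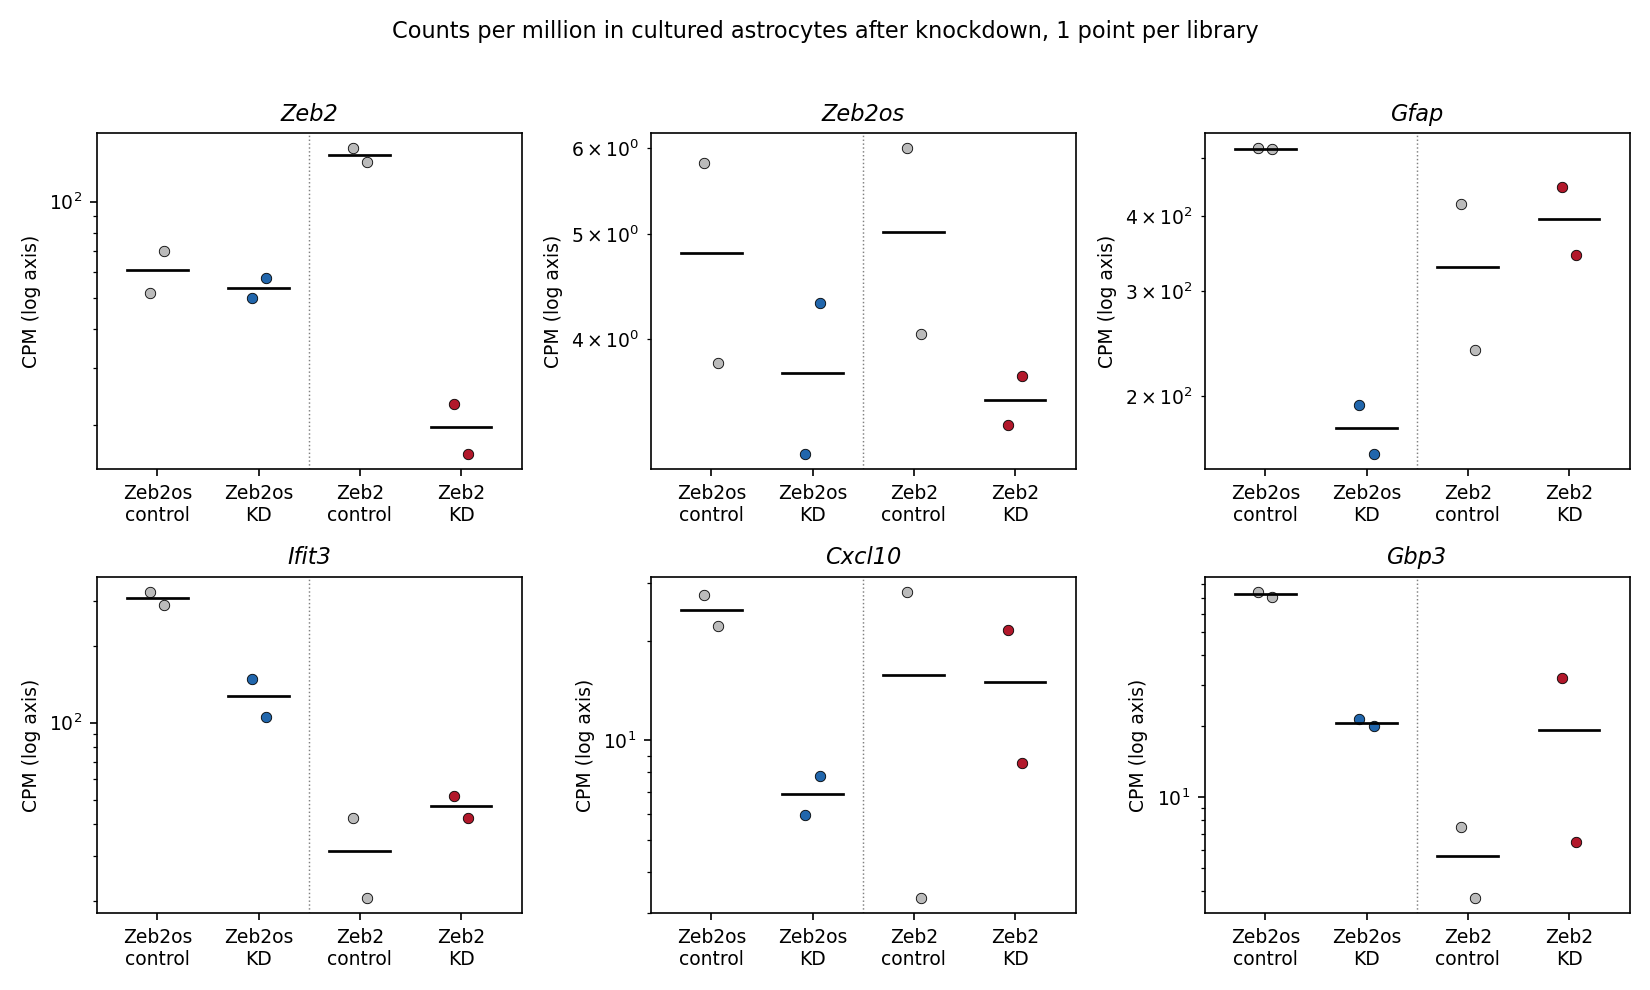
CPM on a log axis of Zeb2, Zeb2os, Gfap, Ifit3, Cxcl10 and Gbp3 in each cultured library, by the label of its group. Zeb2 lay at 147 and 134 CPM in its controls and at 23.2 and 16.1 CPM in the libraries labelled Zeb2 knockdown, while Zeb2os overlapped between groups at 3.14 to 5.82 CPM in its own set.

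Genes called at 7 days with at least 2-fold change, up to 500 per direction, were tested as sets in both knockdowns. In the libraries labelled Zeb2os knockdown, the 7-day risers had a median log2 change of -0.13 (camera adjusted p = 0.0954) and the 7-day fallers one of -0.23 (camera adjusted p = 0.00169), the latter with adjusted p = 0.0840 with an estimated correlation and 0.0513 without knockdown replicate 1. In the libraries labelled Zeb2 knockdown, the risers had a median of -0.18 (camera adjusted p = 0.000251) and the fallers one of 0.21 (0.00203), with adjusted p = 0.307 for both with an estimated correlation. The call of the risers was lost without control replicate 1 (median -0.038, adjusted p = 0.405) or knockdown replicate 1 (0.154), and their median was -0.319 without control replicate 2 and -0.415 without knockdown replicate 2. That of the fallers was lost without control replicate 2 (0.0993) or knockdown replicate 2 (0.0793), and their median was 0.120 without knockdown replicate 1 and 0.324 without control replicate 1.

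Over the 32 lists, camera called 22 at 7 days, 23 at 1 month and 22 at 3 months against sham, 12 from 7 days to 1 month, 18 from 1 to 3 months, 19 in tissue, 13 in the Zeb2os set and 7 in the Zeb2 set. With an estimated correlation, 1 was called in each of the 3 comparisons against sham, mature astrocyte function, and 0 in the others. Median, mean and test also differed in sign for chondroitin sulfate proteoglycans, lymphocyte and oligodendrocyte markers at 1 month, glycolysis and immediate early genes at 3 months, neural stem, p53, lymphocyte, oligodendrocyte, fibroblast and erythrocyte lists from 7 days to 1 month, and mature astrocyte, p53 and fibroblast lists from 1 to 3 months. They did so for glycolysis and Schwann cell lists in tissue, for chondroitin sulfate proteoglycans, cytokines, epithelial and Schwann cell lists in the Zeb2os set, and for A1-type, mature astrocyte, cholesterol, cytokine and ribosomal lists in the Zeb2 set.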

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

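The fits across tables, and the tests of a uniformly lower share of astrocytes, of all Zeb2os counts coming from Zeb2, of too few counts and of a single library carrying the rise in the Zeb2 set, were chosen after the results had been seen.

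Changes from 1 to 3 months differed between sorted cells and tissue in 3256 genes by edgeR (1377 higher and 1879 lower in sorted cells). The fit gave both kinds of sample 1 estimate of spread per gene, though sorted libraries varied more, so it may call too many. For 19 lists camera called the difference, given as the median over genes of the sorted minus the tissue log2 change. These were 1.99 for microglia and macrophage markers, -1.79 for cell cycle, 1.67 for antigen presentation, 1.36 for complement, 1.29 for lysosome and lipid handling, 1.19 for A1-type genes, 1.15 for interferon-stimulated genes, 0.996 for endothelial markers, 0.98 for cytokines, chemokines and NF-kB targets, and 0.89 for pan-reactive genes. The other higher lists were ribosomal proteins at 0.667, oligodendrocyte markers at 0.609, immediate early genes at 0.602, fibroblast and mural markers at 0.483, genes of collagens, laminins and fibronectin at 0.285, TGF-beta and BMP signalling at 0.207 and glycolysis and hypoxia at 0.168. Cholesterol synthesis had -0.694, and chondroitin sulfate proteoglycans and tenascins -0.429. In 9 of the 19 lists, camera called opposite directions in sorted cells and tissue, and all 24 microglia and macrophage markers differed by the edgeR test. With an estimated correlation no list difference passed (smallest camera adjusted p = 0.117).

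Responses of the 2 culture sets were compared in the same way, as the Zeb2os set minus the Zeb2 set. No gene differed by edgeR (1459 at an unadjusted p under 0.05), and camera called 7 lists, with -1.66 for interferon-stimulated genes, -1.39 for microglia and macrophage markers, -1.34 for ependymal markers, -0.858 for neural stem and progenitor genes, -0.831 for mature astrocyte function, 0.544 for ribosomal proteins and 0.540 for endothelial markers. In 2 of these lists camera called opposite directions in the 2 sets. With an estimated correlation none passed (smallest camera adjusted p = 0.296).

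Markers of microglia and macrophages rose in sorted cells after injury. Per the labels' protocols the sort took cells with the Gfap-driven reporter, but its purity was not measured here. A difference in total counts was excluded, since all 20 markers called at 7 days were still called after thinning to the smallest total. At 1 month the median of these markers lay 4.30 above that of ependymal markers (joint SD 1.47). The sort was itself enriched in ependymal markers, so a lower astrocyte share was not excluded. Microglia or macrophages in the sorted material remain a candidate explanation: the markers kept the proportions of whole tissue at 1 month, with an SD of the log2 difference of 0.515, where 1000 random lists of matched expression had a median SD of 1.34 and a 5th percentile of 0.812. Among the abundant markers, Lyz2 and C1qa were at 1263 ± 235 and 849 ± 204 CPM in sorted cells against 2113 ± 451 and 888 ± 127 CPM in tissue, all 24 markers passed the expression filter in tissue, and 3 of them (C1qa, C1qb and C1qc) also stand in the complement list. Uptake of their RNA, debris carrying the reporter or a rise within astrocytes were not tested and stay open.

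Counts of Zeb2os were not lower in the libraries labelled Zeb2os knockdown beyond their spread. Too few counts to see a 4-fold fall were excluded for the count as deposited, since the 95% interval of the log2 change reached down to -1.16 only. In the Zeb2 knockdown the change of Zeb2os lay 2.32 above that of Zeb2 (SE 0.54). Most Zeb2os exonic bases lie outside Zeb2 exons, so Zeb2 may still be the only source. Part of the counts may come from Zeb2 because counting ignored strand: over 96 antisense pairs the long non-coding gene had a median of 1.53 times the counts per kilobase of its coding partner, and 75 pairs were above 0.5. The size of this part, a larger fall of Zeb2os hidden by such counts, a weak knockdown and a wrong label stay open.

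Interferon-stimulated genes had a lower median in the libraries labelled Zeb2os knockdown and a higher median in those labelled Zeb2 knockdown, each against its own controls. A single library behind the fall was excluded, since the highest median of the 4 fits with a library left out was -0.862, without Zeb2os control replicate 1. A single library behind the whole rise was excluded as well, though without Zeb2 knockdown replicate 1 the median dropped to 0.337 from 0.69. The 2 control sets differed, with 26 of 30 of these genes called higher in the controls of the Zeb2os set and a list median of 3.27, against 9 of 30 and 1.17 between the knockdown libraries. The part of this difference in the opposite directions cannot be told apart from an effect of the knockdowns, because the sets share no sample and selection began later after infection in the Zeb2 set. An effect of either knockdown on the interferon response stays open, and a target of the lentivirus other than the intended gene was not tested.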

How the results depend on the processing

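Counts without Lars2 and Gm42418, counts thinned to equal totals and the 2 pairs of gene sets drawn between the knockdowns are tests chosen after the data had been seen, and the planned set of genes called in the Zeb2 knockdown was empty and gave no value. Over the alternatives of the main values, 138 results kept their call or stayed within 1.5 times the count, 52 counts moved further, 19 lost and 1 gained a call and 3 turned direction; of those for named genes, 8473 were kept, 1065 lost and 294 gained a call, and 33 that were not called changed sign or went to 0. No called gene changed sign under any alternative. Zeb2os had 134 to 666 counts per library in its own set. Scaling by RLE, the filter at 1 CPM, the removal of Lars2 and Gm42418 and thinning kept each count of calls within 1.5 times. Counts that moved further were 885 at 3 months against sham in a fit of those groups alone, 1511 by DESeq2, 1406 without a filter and 3560 in a fit of the pair alone for 1 month against 7 days, and 650, 749 and 1277 in the same order for 3 months against 1 month. In the Zeb2os set DESeq2 called 553 and edgeR without a filter 625, and in the Zeb2 set 32 and 142. The cause was not tested. With an estimated correlation, camera called 1 list at 7 days, 1 at 1 month and 1 at 3 months against sham, and 0 in the other comparisons within a table.

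Samples share only a number, with correlations of the deviations of equal numbers between -0.04 and 0.08 in sorted cells, between -0.27 and -0.01 in tissue, at -0.03 in the Zeb2os set and at 0.39 in the Zeb2 set. With the number as a replicate block, edgeR called 4302, 2845, 2710, 631 and 70 genes in the sorted comparisons in the order of the report, 506 in tissue (167 higher and 339 lower), 554 in the Zeb2os set, there with Serpina3n, Timp1 and Aqp4 (adjusted p = 0.000214, 0.00698 and 0.00583), and 80 in the Zeb2 set, there with Zeb2 (adjusted p = 5.31e-05), and camera called 23, 23, 22, 12, 16, 18, 12 and 7 lists.

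Without a single library, calls ran from 2867 (without 7-day replicate 2) to 5504 (without sham replicate 1) at 7 days, from 1727 (without 1-month replicate 3) to 3471 at 1 month, from 1189 (without 3-month replicate 3) to 3540 at 3 months, from 122 to 218 for 1 month against 7 days, and from 7 to 52 for 3 months against 1 month. They ran from 305 to 5980 in tissue, from 20 (without Zeb2os knockdown replicate 1) to 4354 (without Zeb2os control replicate 1) in the Zeb2os set and from 2 (without Zeb2 knockdown replicate 1) to 804 (without Zeb2 knockdown replicate 2) in the Zeb2 set. Where 1 library was left in an arm, it was assumed to vary like the other groups. Shared calls ran from 1517 to 2874 for 7 days and 1 month and from 1008 (without 3-month replicate 3) to 2313 for 1 and 3 months. Besides those in the report, lists that lost a camera call without some library were A2-type, glycolysis, gp130, oligodendrocyte, ribosomal and TGF-beta at 1 month, and chondroitin sulfate proteoglycans, lymphocyte, oligodendrocyte, oxidative phosphorylation, Schwann cell and TGF-beta at 3 months. Further such lists were lysosome and neuron for 1 month against 7 days, cholesterol, complement, ependymal, glycolysis, immediate early, neural stem and precursor markers for 3 months against 1 month, and A1-type in tissue. In the Zeb2os set they were A2-type, complement, endothelial, microglia, neural stem, neuron and oxidative phosphorylation lists, and in the Zeb2 set cell cycle, fibroblast and neuron lists.

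Medians of the 7-day risers in the Zeb2os set were -0.175 for sets of up to 100 genes (camera adjusted p = 0.0172) and -0.160 to -0.062 without a library, and those of the fallers -0.229 with an estimated correlation (adjusted p = 0.0840) and -0.271 to -0.169 without a library. In the Zeb2 set the risers had -0.179 with an estimated correlation (adjusted p = 0.307) and -0.415 (without Zeb2 knockdown replicate 2) to -0.038 (without Zeb2 control replicate 1) without a library, and the fallers 0.212 (adjusted p = 0.307), 0.035 for sets of up to 100 genes (0.381) and 0.120 to 0.324. Tissue risers in sorted cells had -0.242 with an estimated correlation (adjusted p = 0.0755) and -0.314 to -0.199 without a library, and tissue fallers 0.382 (0.136) and 0.291 to 0.453. Genes of smallest p in the Zeb2 set had medians in the Zeb2os set of -0.216 for risers (adjusted p = 0.241 with an estimated correlation), -0.221 for sets of up to 100 genes (0.123) and -0.247 to -0.095 without a library, and of 0.08 for fallers (0.590 with an estimated correlation) and -0.077 (without Zeb2os control replicate 1) to 0.327 (without Zeb2os control replicate 2). Genes called in the Zeb2os set had medians in the Zeb2 set of -0.333 for risers (adjusted p = 0.511 with an estimated correlation) and -2.30 (without Zeb2 knockdown replicate 2) to 0.238 (without Zeb2 knockdown replicate 1), and of 0.813 for fallers (0.511) and -0.019 (without Zeb2 knockdown replicate 1) to 1.70 (without Zeb2 control replicate 1). The cause of these moves was not tested.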

Other observations

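Of the tests below, only the splits were planned. At 1 month after injury sorted cells and tissue differed in 11977 of 23259 genes (5420 higher and 6557 lower in sorted cells). This fit too shared 1 estimate of spread per gene, so its SEs may be too small and its calls too many. Beside the genes of precursors and early response described in the report, all 14 ependymal markers were higher in sorted cells (median log2 difference 2.95, camera adjusted p = 2.0e-07, and adjusted p = 0.256 with an estimated correlation), with the cilia regulator gene Foxj1 at 1.54 ± 0.21 (SE, 3 libraries each). Cell cycle genes were higher in 34 of 35 (median 2.67, camera adjusted p = 2.2e-13, and adjusted p = 0.235 with an estimated correlation). Chondroitin sulfate proteoglycan and tenascin genes were higher in 13 of 18 and lower in 2 (median 1.13, camera adjusted p = 6.3e-07), and kept that call with an estimated correlation (adjusted p = 0.0253). Zeb2 was higher in sorted cells by 1.37 ± 0.10 and the counts assigned to Zeb2os by 0.74 ± 0.14. Slc1a2 and Aldoc, a glutamate transporter gene and a glycolysis gene of astrocytes, were lower by -1.97 ± 0.12 and -2.92 ± 0.09. Sorting and the handling of whole tissue were not separated from the kind of sample, and how many sorted cells were precursors, or astrocytes with low Gfap, stays open.

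Control cultures of the 2 knockdown sets also differed, with 656 genes higher and 334 lower in the controls of the Zeb2os set than in those of the Zeb2 set (edgeR, 2 libraries each). Selection began later after infection in the Zeb2 set, and its length in the Zeb2os set is not settled by the labels. The Y-linked genes Ddx3y and Eif2s3y were lower by -8.53 and -7.72 on the log2 scale in the controls of the Zeb2os set.

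Regrouping the 6 libraries of a comparison into 3 and 3 gives 10 splits, too few for a share under 0.05. The real split called 4440 genes at 7 days against sham, 2927 at 1 month against sham, 633 at 1 month against 7 days and 2889 in tissue, it was the only 1 of the 10 with as many in each, and the highest count of any other split was 0.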
